A study of Homo sapiens with 2 samples.

How the data were processed

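Total RNA from Panc-1 cells was labelled with Cy3 and hybridised to 1-colour Agilent arrays, 1 for DMSO vehicle and 1 for 5 uM Bay41-2272, both at 48 h. The group of each sample was taken from its agent label. Both arrays had the same scan date and array design in the file headers, so these did not differ between the groups. The deposited scanner files gave 62976 features per array, of which 58717 were gene features for 50599 gene probes and 4259 were controls. Processed signals were intensity values that the authors' software had background-subtracted and detrended within each array, with surrogates for low signals and no scaling between arrays, per the file headers. The file headers name Agilent Feature Extraction 10.7.1.1 and the submitters' processing notes name version 9.5.1.1. The mean spot signal and local background were raw intensity values in the deposited files, and flags marked features that were well above background, saturated or outliers.

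A value table of the whole series held 50599 rows per array. Its values were linear intensity that the authors had normalized, and both columns had the same median of 20.5 and the same sorted values. For 100% of ranks these equalled the mean of the sorted processed signals of both arrays within 1%, which is quantile normalization. Each column followed its own array (Pearson r across probes 0.9999 for both) more closely than the other (0.986 and 0.985), so its scale, direction and centring were known. It served as an alternative.

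The main values were log2 of the processed signal minus the array's 75th percentile of it over gene probes. That percentile was 278.8 on the DMSO array and 310.4 on the Bay41-2272 array. Features flagged as outliers (218 and 198 gene features) were left out, spots of 1 probe were averaged, and no feature was saturated. A probe entered when it was well above background on both arrays, as 22123 probes were, and the brightest probe stood for its gene, which left 16688 genes. A further 1646 probes were well above background on the DMSO array only and 643 on the Bay41-2272 array only, and 18015 of 36334 genes were not well above background on either array. For genes seen on 1 array only, the difference is given as a bound against the higher of the dim probe's own signal and the lowest signal among probes well above background on the other array. The median local background was 94 and 103 on the DMSO and Bay41-2272 arrays. The number of arrays limits the precision.

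Gene symbols came from the scanner files, and 28174 probes (55.7%) were named through their RefSeq accession in a table of the GRCh38 assembly, which updated the symbols of 4747 probes. Probe coordinates are those of the files, on hg19. Exon and UTR annotation was not used here. Of the measured genes, 13578 had a symbol that is not a clone or locus name.

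With 1 array per group there was no test. Differences are Bay41-2272 minus DMSO, and genes with a difference of at least 1 or at most -1 on the log2 scale were counted. Before the data were examined, 31 gene lists were fixed, and each list's median difference was set against 10000 random lists of the same size drawn from 20 bins of mean signal. The percentile among them describes these arrays and is not a p-value. Also fixed beforehand was the rule for naming genes. It took the 10 highest and 10 lowest differences among genes with a named symbol whose higher array value reached the median of the probes well above background on that array. It added up to 4 genes per list with the largest absolute difference, the 3 largest bounds each way, and CD44, FOXO3, GUCY1A1, GUCY1B1, PRKG1, PRKG2, PDE5A and VASP. Some genes that met this rule are not reported here. Array error was estimated from 632 probes with about 10 spots each. The SD between spots had a median of 0.0481 on the DMSO array and 0.0483 on the Bay41-2272 array, and the SD of the difference between single spots had a median of 0.0705 and a 95th percentile of 0.224. Different probes of 1 gene differed more, with a median SD of 0.145 over 4003 genes. Of the higher genes 41 had other passing probes and in 35 of these all probes went the same way, as did 30 of 33 among the lower genes.

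Alternatives were normexp background correction (offset 50), scaling to the median of detected probes, quantile normalization, no scaling, scaling to 7 spike-in probes, the authors' value table, other filters on dim probes, other ways to combine probes, and thresholds of 1.5-fold and 3-fold. Removal by lowess (span 0.3) of a trend with signal, or with signal and probe GC content, was added after seeing the data. The procedure was tested on simulated data for the Bay41-2272 against DMSO comparison of 16688 genes. All 50 genes shifted by 1.585 and all 50 shifted by -1.585 passed the 2-fold threshold. So did 1 of 50 at 0.585, 0 of 50 at -0.585 and 0 of the other 16488 genes. A list of 20 of these other genes, shifted by -0.4, came out at -0.38. The simulated noise was that of single spots only, without variation between cultures. The simulation therefore cannot give the rate of false 2-fold differences in the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp, were used.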

Results

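Gene expression was measured in Panc-1, an established line of human pancreatic ductal adenocarcinoma cells, after 48 h with 5 uM Bay41-2272 or with its vehicle, DMSO. Bay41-2272 stimulates soluble guanylate cyclase, the enzyme that makes cyclic GMP (cGMP), and the labels call it a cGMP inducer. Each condition had 1 sample, hybridised to 1 array of a 1-colour Agilent design, so the series held 2 arrays. Each array carried 50599 gene probes, of which 23769 (47.0%) were well above background on the DMSO array and 22766 (45.0%) on the Bay41-2272 array. Both arrays measured 16688 genes, and no difference below has a replicate check or a p-value.

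The comparison asked which transcripts differed between Bay41-2272-treated and vehicle-treated cells. In the treated cells, genes of the integrated stress response, the chaperones of the endoplasmic reticulum and NF-kB target genes were lower as groups relative to all genes, whereas aryl hydrocarbon receptor targets and DNA replication genes were higher as groups. PHLDA1, a pleckstrin homology-like domain gene, was 5.73-fold lower, the cystine transporter gene SLC7A11 was 2.76-fold lower and the chaperone gene HSPA5 was 2.14-fold lower. CYP1B1, a cytochrome P450 under the aryl hydrocarbon receptor, was 2.62-fold higher. Of the 16688 genes, 242 (1.45%) were at least 2-fold higher and 160 (0.959%) at least 2-fold lower on the Bay41-2272 array.

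All differences are Bay41-2272 minus DMSO on the log2 scale after each array was divided by its 75th percentile signal, and their median over all genes was -0.04. The error was estimated from 632 repeated probes: the SD of a difference between single spots had a median of 0.0705, and 0.120 among the dimmest 211 of them. That error covers the arrays and not the cultures. MAML2, a coactivator of Notch signalling, had the largest positive difference among the brighter named genes, 3.75, with log2 signals of -3.07 on the DMSO array and 0.69 on the Bay41-2272 array (probe at hg19 chromosome 11, 95712375 to 95712434). SRD5A3, a reductase of dolichol synthesis, was 8.39-fold higher, PPFIA3 was 5.34-fold higher and UACA was 4.78-fold higher. The small Cajal body RNA SCARNA22 was 4.19-fold higher, and SLC30A1, which exports zinc from cells, was 2.98-fold higher. ZDHHC11 was 3.31-fold higher, with both of its passing probes, those well above background on both arrays, between 1.71 and 1.73. ZSWIM8-AS1, NEURL1B and CASKIN2 were 3.11-fold, 3.02-fold and 2.99-fold higher.

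On the other side, PHLDA1 stood at a log2 signal of 2.85 on the DMSO array and 0.33 on the Bay41-2272 array (probe at hg19 chromosome 12, 76419627 to 76419686). MYO10, an unconventional myosin of filopodia, was 4.33-fold lower. THBD, which encodes thrombomodulin, was 3.12-fold lower and SPNS2, a transporter of sphingosine-1-phosphate, 3.09-fold lower. MIR31HG, the host transcript of miR-31, was 3.15-fold lower and CLCN5 was 3.13-fold lower. Of the probes of SNAI3-AS1, the brightest was 3.70-fold lower while another differed by -0.05. GABRB1, 3.20-fold lower at its brightest probe, had a second probe at 0.16. The probe for 18S ribosomal RNA, RNA18SN5, had log2 signals of 7.73 and 6.15. A single passing probe stood behind 9 of the 10 higher genes named above, and 3 of these lower genes had several.

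**Figure D1:**
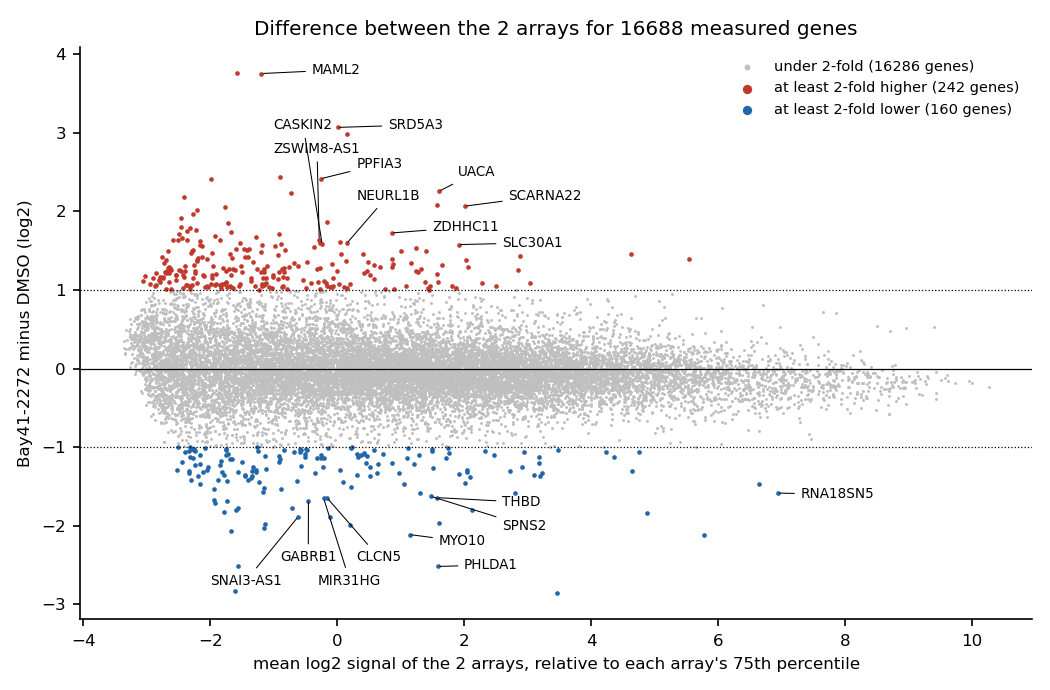
Difference between the arrays (Bay41-2272 minus DMSO, log2) against the mean log2 signal of the 2 arrays for each of the 16688 measured genes, 1 array per condition. Red points mark the 242 genes at least 2-fold higher and blue points the 160 at least 2-fold lower, dotted lines mark 2-fold, and brighter named genes with large differences are labelled, from MAML2 at 3.75 to PHLDA1 at -2.52.

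The integrated stress response list, which holds ATF4 and genes it activates, lay lower as a group. Its 22 measured genes had a median 0.39 below that of all genes, under all 10000 random lists of genes of like signal (percentile 0), and 19 of the 22 were below the median of all genes. SLC7A11 differed by -1.47, the leucine-sensing sestrin SESN2 by -1.21, the glutathione-degrading enzyme CHAC1 by -0.94 and the mitochondrial folate enzyme MTHFD2, read from 10 spots, by -0.82. ATF4 itself, singled out after its value was seen, differed by -0.62. The 3 genes above the median of all genes were SLC7A5, SHMT2 and SLC3A2, at 0.17, 0.05 and -0.04, named like the other exceptions below after their values were seen. The chaperones and folding factors of the endoplasmic reticulum had a median of -0.35 relative to all genes (percentile 0), with 17 of 18 genes below the median of all genes and PDIA4 the exception at -0.02. HSPA5, the main chaperone of that compartment, differed by -1.10 (hg19 chromosome 9, 127997149 to 127997208), CRELD2 by -0.60, EDEM1 by -0.57 and SDF2L1 by -0.56. The cytosolic heat shock proteins did not follow them: their 14 genes had a median of 0.05 relative to all genes (percentile 92.93), with HSP90AB1 at -0.50, HSPA8 at -0.39, HSPA4 at -0.28 and HSPA1B at 0.28. The HSPA1B probe may share signal with its near-identical copy HSPA1A.

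NF-kB targets and cytokines gave the lowest median of all lists, -0.51 relative to all genes (percentile 0), from 12 measured genes of which 11 were below the median of all genes. The signalling adaptor TRAF1 differed by -1.47, NFKB2 by -1.04, the chemokine CCL2, read from 10 spots, by -0.998 and the apoptosis inhibitor BIRC3 by -0.996. CXCL5, at 0.17, was the exception, and IL6, CXCL8 and TNF were not well above background on either array. TGF-beta responsive genes had a median of -0.31 relative to all genes (percentile 0.03), with 11 of 14 below. The cytokine IL11 differed by -0.93 and PMEPA1 by -0.91. The differentiation inhibitors ID2 and ID3 went the other way, at 1.196 and 0.59, and SKIL stood at 0.03. Genes of the MAPK feedback list had a median of -0.24 (percentile 0.25) with 13 of 16 below the median of all genes, among them PHLDA1 at -2.52, EPHA2 at -0.49, ETV5 at -0.46 and SPRY4 at -0.48, whose other probe stood at 0.19. EPHA4, DUSP4 and IER3 were the 3 exceptions, at 0.41, 0.29 and -0.03. Glycolysis and hypoxia genes had a median of -0.26 (percentile 0.03) with 19 of 22 below. ANGPTL4 differed by -0.95, hexokinase HK2 by -0.63, the glucose transporter gene SLC2A1 by -0.62 and the kinase PDK1 by -0.60, whereas BNIP3L, HK1 and ADM stood at 0.13, 0.05 and 0.04.

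**Figure D2:**
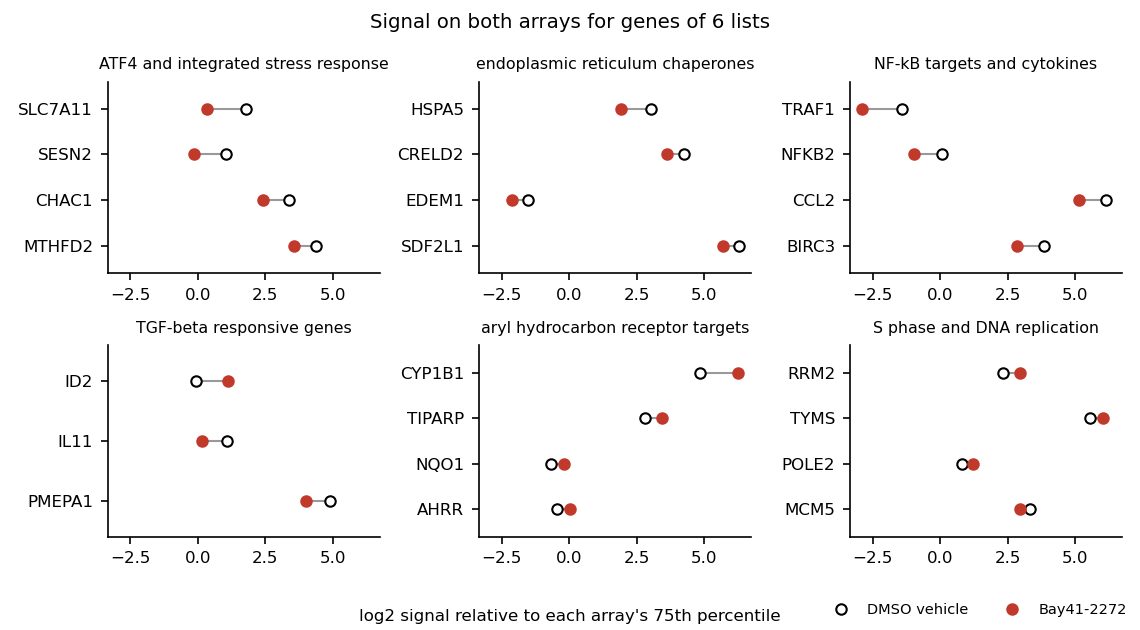
Log2 signal relative to each array's 75th percentile on the DMSO array (open points) and the Bay41-2272 array (red points) for 3 or 4 of the genes with the largest differences in each of 6 gene lists, 1 array per condition. The grey line joins the 2 values of a gene, such as 1.78 and 0.32 for SLC7A11. Over the 50 repeated probes nearest in signal, the median SD of a difference between single spots was 0.0435 for CCL2 and 0.237 for the dim TRAF1.

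Ribosomal protein genes were lower by a small amount: all 25 lay below the median of all genes, from RPS4X at -0.063 to RPL3 at -0.49, with a median of -0.22 relative to it (percentile 0.43). RPLP0, RPL13A and RPL7 followed RPL3 at -0.45, -0.45 and -0.42. Differences also went with signal, from a median of 0.10 in the dimmest decile of genes to -0.11 in the brightest decile, where these genes lie. When that trend was removed by lowess, the ribosomal median relative to all genes was -0.07 (percentile 3.63). Epithelial markers had a median of -0.19 (percentile 2.19), with 13 of 17 genes below the median of all genes, but lay outside the random range under only 10 of 13 other settings, with a percentile of up to 16.17. The laminin gene LAMB3 differed by -0.77 and the keratin genes KRT8 and KRT18 by -0.49 and -0.37. The 4 exceptions were CLDN3, CDH1, CLDN7 and ESRP2, at 0.96, 0.30, 0.16 and 0.00465.

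Aryl hydrocarbon receptor targets had the highest median, 0.51 above all genes (percentile 99.95), and all 6 measured genes were above the median of all genes. CYP1B1 differed by 1.39 at its brightest probe (hg19 chromosome 2, 38295444 to 38295503) and by 1.42 at the other. TIPARP differed by 0.60, NQO1 by 0.48 and the receptor's repressor AHRR by 0.46. CYP1A1, the classical target of the receptor, was well above background on the Bay41-2272 array only, where it was at least 3.27-fold higher; it was singled out after its value was seen. S phase and DNA replication genes had a median 0.25 above all genes (percentile 99.99), with 21 of 25 above. The ribonucleotide reductase subunit RRM2 differed by 0.66, thymidylate synthase TYMS by 0.46 and POLE2 by 0.42. MCM5 at -0.37, MCM6 at -0.33 and CHAF1A at -0.26 were among the 4 exceptions. G2/M and mitosis genes had a median 0.12 above all genes (percentile 99.44), with 20 of 25 above. The topoisomerase TOP2A, read from 10 spots, differed by 0.69, NUSAP1 by 0.66, KIF20A by 0.47 and AURKB by 0.44. CENPE at -0.36, HMMR, BUB1B, CENPF and DLGAP5 were the 5 genes below. Without a filter on dim probes, the G2/M median lay at -0.085 relative to all genes, that of S phase genes at 0.045 and that of aryl hydrocarbon receptor targets at 0.21, and all 3 were still above the central 95% of random lists.

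**Figure D3:**
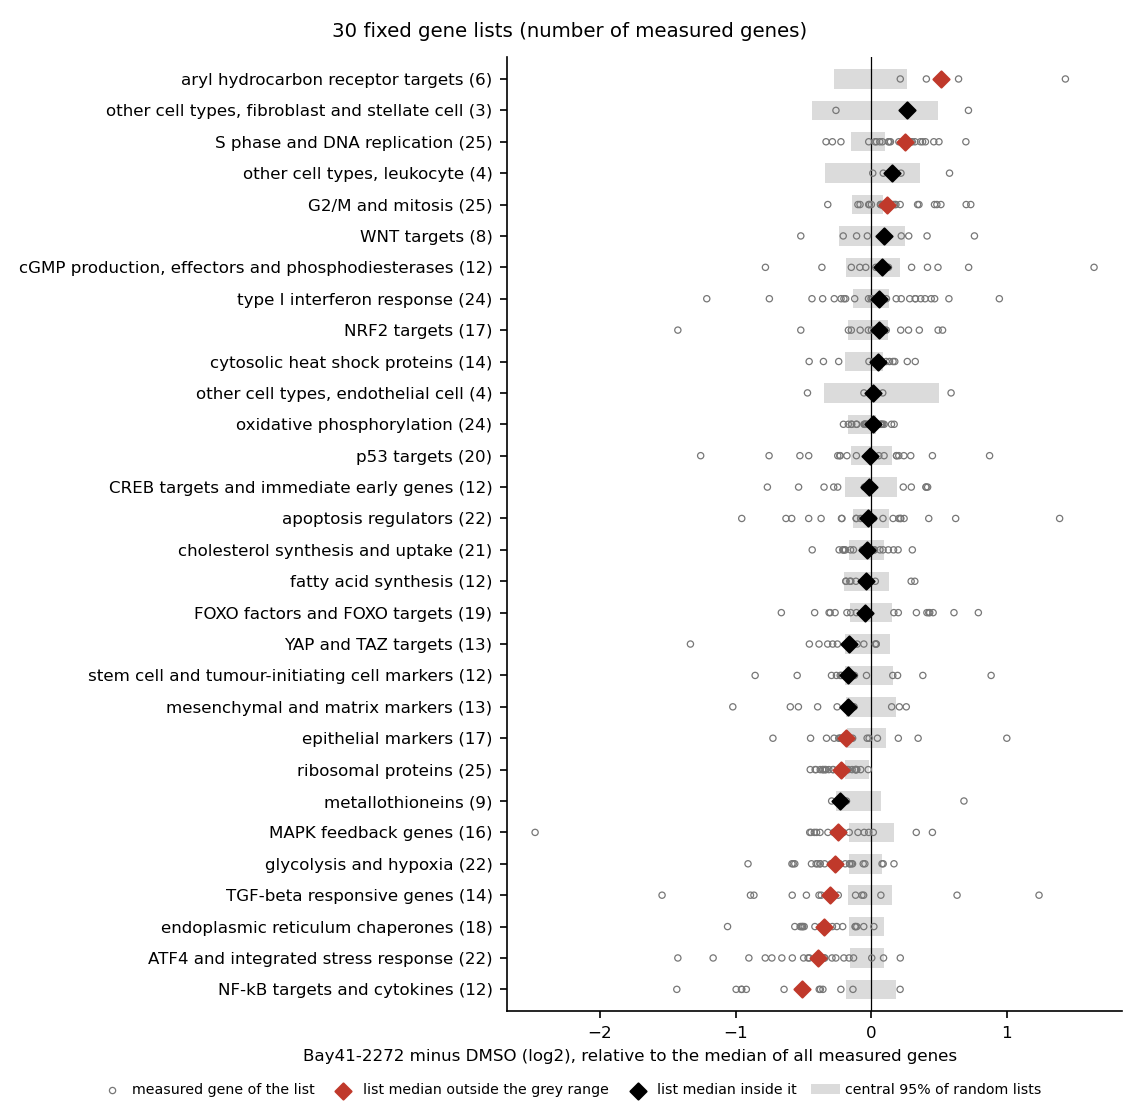
Difference between the arrays (Bay41-2272 minus DMSO, log2) relative to the median of all genes for 30 gene lists, with 1 open circle per measured gene, a diamond at the list median and a grey bar over the central 95% of 10000 random lists matched on signal. Red diamonds mark the 11 lists outside that range, 3 above and 8 below, from 0.51 for aryl hydrocarbon receptor targets to -0.51 for NF-kB targets.

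Much of the cGMP pathway was near background. No probe of GUCY1A1 or GUCY1B1, which encode subunits of soluble guanylate cyclase, nor of the cGMP-dependent kinases PRKG1 and PRKG2, was well above background on either array. GUCY1A2, which encodes another subunit, was well above background on the DMSO array only, where it was at least 1.25-fold higher; it was looked up after the data were seen. The 12 measured genes of the cGMP list had a median 0.08 above all genes (percentile 77.48). PDE2A, a phosphodiesterase stimulated by cGMP, was 3.03-fold higher from a dim signal of -2.33, and NOS3, the endothelial nitric oxide synthase, differed by 0.68. PDE10A differed by -0.82. The probes of the cyclic nucleotide exporter ABCC5 disagreed, from -0.66 to 0.45. PDE5A, which degrades cGMP, and the kinase substrate VASP differed by -0.08 and -0.13, and both turned positive under scaling to the spike-ins. CREB targets and immediate early genes had a median of -0.02 relative to all genes (percentile 47.73), with JUN at -0.81, ATF3 between -0.58 at its brightest probe and 0.09 at another and EGR1 at 0.37, and the median was -0.25 among brighter probes.

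Stem cell and tumour-initiating cell markers had a median of -0.17 relative to all genes (percentile 4.49), with 8 of 12 below. CD44, a hyaluronan receptor, was 1.86-fold lower at its bright probe, from 7.91 to 7.02 (hg19 chromosome 11, 35253812 to 35253871). Its dim probe, for transcript variant 8, differed by 0.83 (35244791 to 35244850). The drug exporter ABCG2 differed by 0.84, NES by -0.59 and ALDH1A3 by 0.34. FOXO factors and their targets had a median of -0.04 (percentile 28.97), with PINK1 at 0.75, KLF6 at -0.70 at its brightest probe and 0.35 at another, FOXO1 at 0.57 and SOD2 at -0.46. That median was 0.19 among brighter probes and -0.25 without a filter on dim probes. FOXO3 differed by -0.19 at its brightest probe, with its 3 probes between -0.45 and -0.19, and the value was positive under scaling to the spike-ins.

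Mesenchymal and matrix markers had a median of -0.17 relative to all genes (percentile 3.60), with 10 of 13 below, including the collagen genes COL1A1 at -1.06 and COL5A1 at -0.64 and vimentin, VIM, at -0.58. YAP and TAZ targets had a median of -0.17 (percentile 5.24). Among them NT5E, the ecto-nucleotidase CD73, was 2.59-fold lower and its other probe stood at -1.78, while CCN1 and CCN2 differed by -0.50 and -0.43. Metallothioneins had a median of -0.23 (percentile 4.13) with 8 of 9 below, MT1F being the exception at 0.64, and their probes may share signal between near-identical members. WNT targets lay at 0.10 relative to all genes (percentile 78.45), with RNF43 at 0.72 and DKK1 at -0.56. The type I interferon list lay at 0.06 (percentile 82.60), and its members went both ways, with IFIT2 2.38-fold lower, IFIT3 at -0.79, IFI27 at 0.90 and OAS2 at 0.53, and the median was 0.21 among brighter probes.

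Targets of p53 had a median of -0.01 relative to all genes (percentile 43.94), with GDF15 at -1.30, PLK3 at -0.79 and BTG2 at 0.83. Apoptosis regulators lay at -0.03 (percentile 39.81), with the BH3-only gene BMF at 1.35, BCL2L1 at -0.67 and BAD at -0.63. NRF2 targets lay at 0.06 (percentile 86.38), with SLC7A11 at -1.47 and the probes of the exporter gene ABCC3 at 0.45 and -1.52. The lists of cholesterol synthesis and uptake (-0.03, percentile 46.47), fatty acid synthesis (-0.04, percentile 49.88) and oxidative phosphorylation (0.01, percentile 92.51) stood close to all genes. HSD17B7 at -0.48, ACSL3 at 0.28 and ATP5PO at -0.25 were their furthest members, and the 4 probes of HSD17B7 well above background on both arrays disagreed, from -0.48 to 0.43.

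Markers of other cell types were sparse. Of the fibroblast and stellate cell markers 3 of 12 were measured, of the leukocyte markers 4 of 12, of the endothelial markers 4 of 10 and of the pancreatic acinar and islet markers 1 of 12. The first 3 of these lists had medians of 0.26, 0.15 and 0.02 relative to all genes (percentiles 86.33, 82.23 and 41.08), with THY1 at 0.68, PDGFRA at -0.30, CD14 at 0.54 and ESAM at -0.51. VWF differed by 0.55 at a dim probe, while its other probes were not well above background on either array. CEL, the acinar marker measured on both arrays, differed by -0.07. PRSS1, of the same list, was well above background on the DMSO array only, where it was at least 4.29-fold higher.

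A further 440 genes were well above background on the Bay41-2272 array only and 1178 on the DMSO array only. Set against the higher of the dim probe's own signal and the lowest signal well above background on the other array, 175 and 73 of them were at least 2-fold apart. After scaling, that lowest signal was higher on the Bay41-2272 array than on the DMSO array, so these counts are not directly comparable between the directions. RYR2, a ryanodine receptor, was at least 10.0-fold higher on the Bay41-2272 array at 1 probe, while its other probe was not well above background on either array (-5.82 and -5.46). On the same array ISM1 was at least 8.33-fold and LYG1 at least 8.06-fold higher. MIR4500HG was at least 4.73-fold higher on the DMSO array, GRIP2 at least 4.40-fold and PRSS1, cationic trypsinogen, at least 4.29-fold. The other probes of GRIP2 were not well above background on either array.

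The split between the 242 higher and 160 lower genes (60.2% higher) depended on scaling, filtering and background correction, being 79.7% higher without scaling, 94.9% when scaled to the spike-ins, 48.8% with normexp background correction and 46.2% among brighter probes. Scaling to the spike-ins added 0.394 to each difference, so that list medians relative to all genes stayed where they were while single genes between -0.39 and 0 changed sign. Taken by themselves, not relative to all genes, the medians of the NF-kB and integrated stress response lists were then -0.16 and -0.039 and that of the endoplasmic reticulum chaperones 0.0042, and the other 5 lists below the random range were above 0.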

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

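The results were recomputed under 13 other settings and 2 other thresholds, and no paired analysis was possible because each group held 1 array. Of the 242 higher and 160 lower genes, 234 and 151 stayed past 2-fold with quantile normalization and 60 and 65 with normexp correction. Median scaling, no scaling and spike-in scaling add a positive constant to each difference, which keeps the higher genes by construction, and they left 149, 97 and 46 of the lower genes. Of 438 values of the 34 named genes past 2-fold, 416 stayed past it in the same direction. Many of these values could not change. The constant scalings keep the higher genes, and for a gene with 1 passing probe other ways to combine probes return the main value. The filters on dim probes seldom replace a gene's brightest probe. The 416 are therefore not a measure of robustness. The lists of the integrated stress response, endoplasmic reticulum chaperones, NF-kB targets, glycolysis and hypoxia, aryl hydrocarbon receptor targets, S phase and G2/M lay outside the central 95% of random lists under all 13 settings, TGF-beta responsive and MAPK feedback genes and ribosomal proteins under 12 and epithelial markers under 10. For these lists the 3 constant scalings cannot change the outcome and count among the 13. The authors' value table is itself quantile normalized and gave the same counts as that setting, 241 higher and 159 lower genes. Quantile normalization and the value table are thus not separate checks of the lists or the named genes. A threshold of 1.5-fold gave 916 higher and 803 lower genes and one of 3-fold gave 40 and 29. Normexp correction, which also starts from the raw mean signal and local background, gave 62 higher and 65 lower genes, 11 genes at least 2-fold apart by bound on the DMSO array only and 20 on the Bay41-2272 array only, and a spot SD of 0.146. No scaling gave 382 higher and 97 lower genes. Spike-in scaling gave 861 and 46, with bounds for 27 genes on the DMSO array only and 354 on the Bay41-2272 array only. Relative to all genes, ribosomal proteins moved to -0.10 with quantile normalization, to -0.10 in the authors' value table, to -0.075 with lowess on signal and to -0.080 with lowess on signal and GC. Probes well above background on at least 1 array gave 569 higher and 531 lower genes. Without a filter on dim probes, 2063 genes were higher and 1195 lower. That setting shifted the median of all genes by 0.202 because it let in probes at background, and the lists that moved relative to it all moved down. G2/M reversed to -0.085, and the others that moved were FOXO -0.25, S phase 0.045, aryl hydrocarbon receptor 0.21, epithelial -0.40, mesenchymal -0.36, YAP and TAZ -0.37, MAPK feedback -0.44, integrated stress response -0.59, endoplasmic reticulum chaperones -0.55, heat shock -0.15, cholesterol -0.22, fatty acid -0.25, interferon -0.090, p53 -0.21, NRF2 -0.11, apoptosis -0.23, metallothioneins -0.43, ribosomal proteins -0.43 and oxidative phosphorylation -0.19. Among brighter probes 67 genes were higher and 78 lower, CREB targets moved to -0.25, FOXO targets to 0.19 and interferon genes to 0.21, each then outside its random range. GABRB1 reversed to 0.16 at its probe with the smallest difference. Except where a construction is named, the cause was not tested. Signal over background limited dim genes most: the SD of single-spot differences was 0.120 among the dimmest 211 repeated probes, 0.0678 among the middle 210 and 0.0507 among the brightest 211.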

Other observations

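Gene families named by the letters that open their symbols were set against random lists in the same way, a grouping chosen after seeing the data. Of 228 families with at least 8 measured genes, 25 lay outside the central 95% of random lists, 14 below and 11 above. The number expected by chance, 11.4, holds only if members of a family vary independently, and some share probe signal. The excess is therefore a description only. Box C/D small nucleolar RNAs (SNORD) had 101 of 134 members lower and a median of -0.21 (percentile 0). SNORD50B differed by -1.77, SNORD47 by -1.33 and SNORD116-27 by 1.07. Box H/ACA small nucleolar RNAs (SNORA) had a median of -0.15 (percentile 0.02), with SNORA61 at -1.34 and SNORA12 at 1.29. Whether the SNORD and SNORA probes read these small RNAs or transcripts of their host genes, described below, was not tested. Translation initiation factors (EIF) had 42 of 51 genes lower, a median of -0.22 (percentile 0.03) and EIF3C at -0.84, and elongation factors (EEF) a median of -0.26 (percentile 1.57). Under scaling to the spike-ins, which adds 0.394 to each difference, all 4 of these medians were above 0, while their percentiles do not depend on such a shift.

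Other families lay high. The small NF90-associated RNAs (SNAR), whose near-identical copies share probe signal, had a median of 0.62 (percentile 100), with SNAR-F at 0.81 and SNAR-C4 apart at -1.06. Genes whose symbols open with CDKN, most of them inhibitors of cyclin-dependent kinases, were higher in 8 of 9 cases, with a median of 0.25 (percentile 99.72), CDKN1C at 0.70, CDKN2C at 0.68 and CDKN1A at 0.25. They stood high beside the higher S phase and G2/M lists. Zinc finger genes (ZNF) had a small positive median, 0.04 over 430 genes (percentile 99.99). Receptors of the tumour necrosis factor family (TNFRSF) had a median of -0.27 (percentile 0.74), which spike-in scaling also turned positive.

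In the patterns that follow, the tests of single-spot error for the host genes and for CD44 were chosen after the result was seen, as was the lowess correction as a setting. Medians here are not relative to all genes. The median of all genes was itself -0.04 before lowess on signal and GC and 0.004 after it, so part of each change is recentring. The lower integrated stress response and chaperone lists held 40 genes with a median of -0.42. After lowess correction on signal and probe GC content the median was -0.35, against a central 95% of -0.08 to 0.09 for random lists. That outcome was nearly fixed beforehand, because the lists were picked for lying below random lists already matched on signal. Across bins of probe GC content the median difference ran only from 0.0044 to -0.092. The correction shows that trends of this size leave most of the median, and is no separate support. A difference in RNA integrity would part probes near the 5' and 3' ends, but over 2105 transcripts the 5' probe's difference minus the 3' probe's had a median of -0.024 (95% bootstrap interval -0.0379 to -0.00918). That interval was wholly negative, though within the bound of 0.1 in size. The 40 genes were not tested apart from the other transcripts. A lower stress load in the treated culture, from the compound or from medium and cell density at harvest, may account for the pattern, and 1 culture per group leaves these untested.

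Host genes of small nucleolar RNAs and ribosomal protein genes, many of which share a terminal oligopyrimidine start, were lower. The 20 host genes had a median of -0.51, with SNHG5 at -1.47, SNHG12 at -1.35, SNHG3 at -1.07, GAS5 at -0.96 and ZFAS1 at -0.93, and the 18 probes of SNHG5 ranged from -1.55 to -1.46. Of the 20, 15 lay below the median of all genes by over 2 SD of single-spot differences, with 3 above by as much. Spot error is thus not the whole cause. The difference over all genes had an SD of 0.386, however, so passing that cut does not set the host genes apart. After lowess on signal and GC the host genes' median was -0.46 (random range -0.11 to 0.13). The host genes already lay below random lists matched on signal, so this outcome too was nearly fixed beforehand and is no separate support. For 82 ribosomal protein genes the same correction took the median from -0.24 to -0.058 (random range -0.03 to 0.07), so that most of their shift went with the trend. A lower level of terminal oligopyrimidine transcripts in the treated culture may account for the host genes and the remainder, as a hypothesis that these 2 arrays cannot separate from a difference between cultures.

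The CD44 probes differed in opposite directions, by -0.90 at the bright probe for transcript variant 1 and others and by 0.83 at the dim probe for variant 8. The dim probe's difference was 7.01 times the SD of single-spot differences at its signal, 0.118. After lowess on signal and GC the probes still differed by 1.61, against 1.72 before. Those trends were too small to close such a gap, with medians from 0.10 to -0.11 across signal deciles, so that outcome was fixed beforehand. A shift between CD44 transcripts may be behind the opposite directions, as a hypothesis. Binding of other transcripts by the dim probe stays open and was not tested.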
